A study of Homo sapiens with 27 samples.

How the data were processed

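Total RNA from 3 chemotherapy-resistant sublines of human castration-resistant prostate cancer lines (DU145-DR, 22Rv1-DR and ARCaPM-DR) was sequenced after expression of a control hairpin or of either of 2 short hairpin RNAs against the transcription factor GATA2, here called shGATA2a and shGATA2b. The labels give 3 replicates for each of the 9 groups, 27 libraries in all. Per the labels' protocols, RNA was isolated with the RNeasy Mini kit and libraries followed a standard Illumina protocol. Per the submitters' processing notes, TopHat2 version 2.0.9 and Cufflinks version 1.3.0 were used with the hg19 (GRCh37) build. The program that counted reads, the scaling tool and whether counting used strand are not given in the sources used here. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

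The authors deposited 1 table of 23228 gene symbols by 27 libraries, with no duplicated symbol (0). The unit was found from the values. In each library the deposited signal was a whole multiple of a single step, as read counts per gene divided by one size factor per library are, and not a value divided by gene length. Whole reads were recovered by dividing each value by the library's step. Of 433407 values above 0, 99.954% lay within 0.005 reads of a whole number. The other 199 values, in 58 genes, did not, and how they arose is not given in the sources used here. The test design was written before the data were examined and assumed FPKM or counts. Because the values were scaled counts, limma was run on the deposited scale as the design had set for normalised values. The filter became a value of at least 10 in at least 3 libraries and the minimum mean for a named gene became 50, both chosen after the unit was known and before any test result.

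Recovered reads per library ranged from 3.44 to 19.40 M, with a median of 12.87 M. With 1 read as the step, a gene with 0 reads in a library could hold up to 3 reads there at the counting limit, and such limits cover counting error only. Replicates of a group differed by more than counting noise: the chi-square per degree of freedom between replicate pairs ran from 6.8 to 112, so no pair of replicates of a group held the same library. Correlations of log2 values between replicates ran from 0.9647 to 0.9931.

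Each line was fitted alone with limma (version 3.58.1, R 4.3.3) on log2(value + 1), with a mean-variance trend and no covariate. Fold changes are on that scale, which understates changes of low genes. The knockdown contrast was the mean of both hairpin groups minus the control, and each hairpin was also set against the control and against the other. A joint fit of all 27 libraries gave the average knockdown effect over the lines and a test of whether the effect differed between them. Adjusted p-values are Benjamini-Hochberg within a contrast, with a threshold of 0.05. "Rose" and "fell" mean past that threshold. Gene lists of known processes were fixed before the data were examined and tested against all other genes with camera at a preset inter-gene correlation of 0.01, where at least 5 members were measured. Camera with an estimated correlation and fry were alternatives.

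Named genes followed a rule written before the data were examined. It took, among others, GATA2, GATA3, KLK3, IGF2, IGF1R, INSR, FOXM1 and POM121, then in each line the 10 genes up and the 10 down with the largest fold among those past the threshold, where all 6 knockdown libraries lay on the same side of all 3 controls. It also took the genes called in all 3 lines, up to 4 members of each list with the smallest adjusted p, and the 5 genes with the smallest p for a difference between lines. Outside the rule, VIM and the levels of ABCB1 in controls describe the lines. For the hairpin difference the rule took the 3 genes up and the 3 down with the largest fold.

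The replicate numbers in the labels were tested for pairing. In each line, deviations from the group means of same-numbered libraries were correlated over all 9 pairs. The lowest correlations were 0.39 in DU145-DR, 0.26 in 22Rv1-DR and 0.13 in ARCaPM-DR, with medians of 0.52, 0.44 and 0.69. Medians for other numbers were -0.26, -0.24 and -0.40. Deviations from a group mean sum to 0, so these negative medians are no separate evidence. In these lines 9, 9 and 8 of 9 libraries correlated best with a library of their own number, so the numbers pair the samples. Counts with the replicate number as a block are given beside the main counts where they moved by over 1.5 times. The pairing comes from the data, since the labels do not say what a number marks.

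Alternatives were another pseudocount (0.1), no filter, a filter of 50, quantile normalisation, median of ratios scaling, the replicate block, no trend, a fold threshold, 1 fit of all libraries and leaving out each library. Alternatives added after the data were seen left out the 58 genes, with and without the block, removed round offsets from their values, or ran edgeR (version 4.0.16) and DESeq2 (version 1.42.0) on the recovered reads, with values that were not whole rounded. Keeping duplicated symbols apart would have changed nothing and was not run. The tests were run first on simulated counts. With the spread of each line, limma recovered 95.52% of simulated 2-fold changes in DU145-DR, 79.10% in 22Rv1-DR and 73.13% in ARCaPM-DR, and 64.18%, 10.45% and 22.39% of simulated 1.5-fold changes. Reads of near-identical genes, such as POM121 and POM121C or the histone genes, and of overlapping or antisense genes cannot be told apart with certainty. No coordinates are given, since no hg19 annotation was used here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.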

Results

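Transcript levels were measured by RNA sequencing in DU145-DR, 22Rv1-DR and ARCaPM-DR, chemotherapy-resistant sublines of human prostate cancer lines. Each line carried a control hairpin, shGATA2a or shGATA2b, with 3 libraries per group and 27 in all. Values are normalised read counts as the authors deposited them. Median recovered depth was 13.20 M reads in DU145-DR, 13.02 M in 22Rv1-DR and 10.75 M in ARCaPM-DR, and the shallowest library, ARCaPM-DR shGATA2a replicate 3, held 3.44 M. The table lists 3358 genes at 0 in every library. The lines differed in their baseline. VIM, a mesenchymal intermediate filament, stood at 13011 ± 528 (SD, n = 3) and 47215 ± 7786 in DU145-DR and ARCaPM-DR controls and at 89.9 ± 49.3 in 22Rv1-DR.

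A property of the table bears on the genes named here. Among values above 0, 199 values in 58 genes were not a whole number of reads, within a tolerance of 0.005 reads, while 99.954% of values were. IGF2 had 23 such values among its 27, GATA2 and POM121 had 12 each and FOXM1 had 8. Of the 199, 148 were in control libraries and 51 in knockdown libraries, and 142 were in 22Rv1-DR, 41 in DU145-DR and 16 in ARCaPM-DR. Removing a multiple of 100 normalised reads, up to 10 multiples above or below, made 137 of them whole within 0.0005 reads, whereas 90 comparison bases made 3.2 whole on average and 31 at most. Main counts of genes are therefore given with and without these 58 genes.

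**Figure D1:**
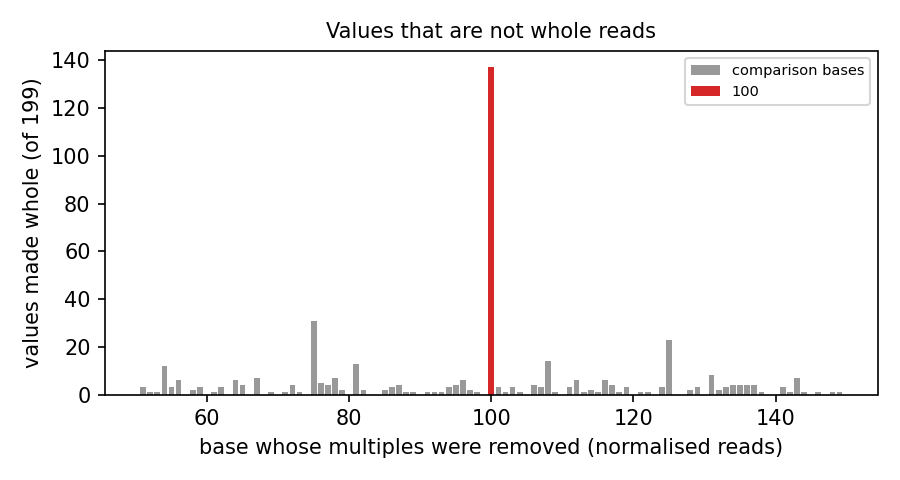
Number of values, out of the 199 that were not a whole number of reads, that became whole after removing a multiple of the base on the horizontal axis (normalised reads). The red bar is the base 100, with 137 values, and the grey bars are the 90 comparison bases, of which the highest reached 31.

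GATA2, the hairpins' target and a zinc finger transcription factor, fell in all 3 lines. In ARCaPM-DR, where all of its values were whole, it went from 157 ± 14.4 (SD, n = 3) in controls to 34.6 ± 10.6 with shGATA2a and 19.7 ± 2.23 with shGATA2b (log2 fold change -2.56, SE 0.22, adjusted p = 8.8e-05 by limma). In DU145-DR it went from 1105 ± 167 to 282 ± 54.9 and 332 ± 60.6 (log2 fold change -1.85, SE 0.15, adjusted p = 5.5e-05), with 5 of 9 values not whole. Removing the round offsets found for those 5 values, a setting chosen after the data were seen, gave 871 ± 127 in controls and 309 ± 40.9 in knockdowns (log2 fold change -1.49, SE 0.13, adjusted p = 7.5e-05). In 22Rv1-DR it went from 3601 ± 642 to 1051 ± 264 and 1215 ± 476 (log2 fold change -1.71, SE 0.24, adjusted p = 0.0256), but 7 of 9 values were not whole. Only Control replicate 1 (3444) and shGATA2b replicate 2 (1738) were whole there, so GATA2 is a limited check of the 22Rv1-DR labels. The call there was also lost without any 1 of 7 libraries (adjusted p 0.063 to 0.11) and without a trend (0.0571). An exact two-sided permutation test of 6 knockdown against 3 control libraries gave p = 0.0119 in each line, the smallest that 84 splits allow, and 3 against 3 cannot go below 0.1.

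**Figure D2:**
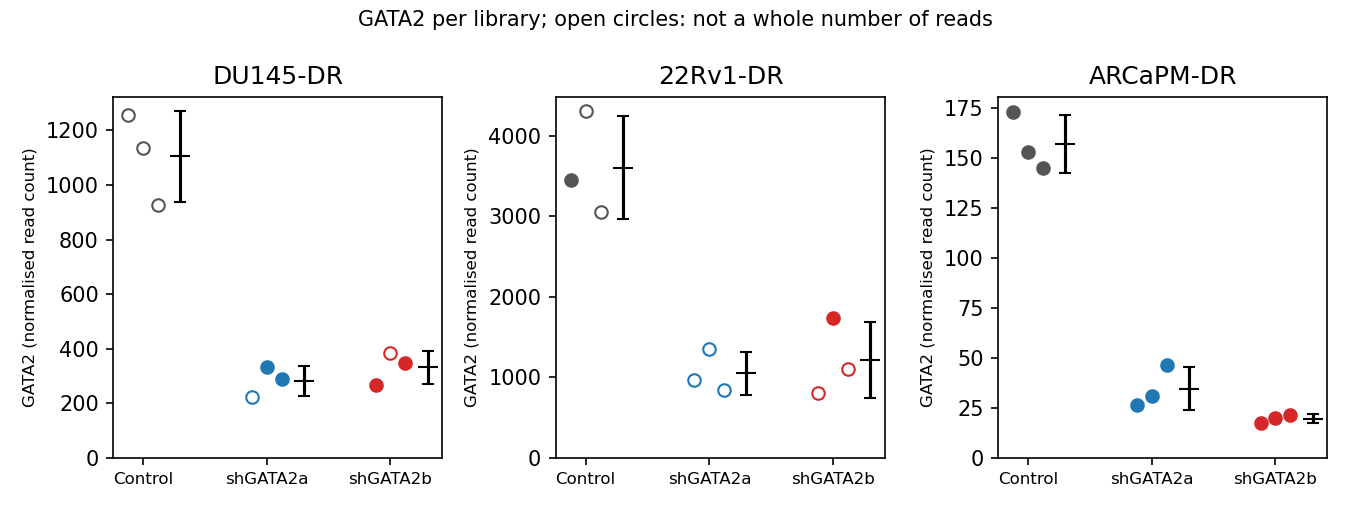
GATA2 per library in normalised read counts, by group and cell line, with the mean and SD (n = 3) to the right of each group. Open circles are values that were not a whole number of reads, 5 in DU145-DR, 7 in 22Rv1-DR and 0 in ARCaPM-DR, and every control library lies above every knockdown library of its line.

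Among the other genes named in advance, IGF2, the insulin-like growth factor ligand, fell in DU145-DR from 125 ± 32.7 to 20.6 ± 6.12 (adjusted p = 2.0e-04), in 22Rv1-DR from 96.5 ± 18.4 by a log2 fold change of -2.37 (adjusted p = 0.0256) and in ARCaPM-DR from 181 ± 8.06 to 28.2 ± 7.47 (adjusted p = 6.3e-05). Since 7, 8 and 8 of its 9 values per line were not whole, its level is uncertain in all 3. A single round offset could be assigned to part of these values, which does not show that it was added to any one of them. With the assigned offset removed, the DU145-DR IGF2 controls of 126, 158 and 92.5 became 26.1, 27.8 and 22.5, with knockdown values of 7.20, 8.48 and 16.7 after removal, 12.1 and 16.0 that were whole, and 23.4 with no offset found. In 22Rv1-DR, IGF2 in Control replicates 2 and 3 went from 78.9 and 115.7 to 8.93 and 5.71, beside knockdown values of 4.63 and 6.31 after removal and 16.2 that was whole. No single offset was found there for Control replicate 1 (94.7) or for knockdown values of 18.9, 8.44 and 29.3. In ARCaPM-DR, IGF2 in Control replicate 1 went from 189 to 88.6, with knockdown values of 6.97 to 17.5 after removal and 23.3 that was whole, and Control replicates 2 and 3 (173 and 183) had several possible offsets. The change of IGF2 could not be refitted in any line. POM121, a nuclear pore protein with a near-identical copy, fell in ARCaPM-DR (log2 fold change -1.03, SE 0.13, adjusted p = 6.4e-04, 3 of 9 values not whole) and DU145-DR (-0.94, SE 0.20, adjusted p = 0.00891, 1 of 9). In ARCaPM-DR the POM121 values not whole were those of shGATA2a: removing the assigned offset took replicates 1 and 3 from 686 and 758 to 1186 and 1158, beside controls of 1381 ± 44.1, and replicate 2 (559.7) had none. The shGATA2b values there were whole (697 ± 90.2, log2 fold change -0.99, adjusted p = 0.00213). In 22Rv1-DR its log2 fold change was -0.78 with adjusted p = 0.105 and 8 of 9 values not whole. FOXM1, a transcription factor of mitotic genes, fell in DU145-DR (-0.83, SE 0.15, adjusted p = 0.00365, 3 of 9), and with round offsets removed the change there was -0.54 (adjusted p = 0.0323). FOXM1 did not pass in 22Rv1-DR (-0.84, adjusted p = 0.0917, 3 of 9) or ARCaPM-DR (-0.68, adjusted p = 0.0676, 2 of 9). With the replicate block FOXM1 passed in both (adjusted p = 0.00812 and 7.1e-06), as did POM121 in 22Rv1-DR (0.0102). With round offsets removed and no block, FOXM1 in 22Rv1-DR had 718 ± 311 in controls and 551 ± 118 in knockdowns (log2 fold change -0.31, SE 0.28, adjusted p = 0.693). GATA3, IGF1R and INSR passed in no line without the block, and KLK3 (-1.37, adjusted p = 0.111, 1 of 9) did not in 22Rv1-DR. With the block KLK3 (0.0231) passed in 22Rv1-DR, and IGF1R (-0.34, adjusted p = 0.00446) and INSR (-0.41, adjusted p = 0.00209) in ARCaPM-DR. KLK3 was too low to test in the other lines.

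In DU145-DR, MET, a receptor tyrosine kinase, rose from 999 ± 155 (n = 3) to 2675 ± 314 (n = 6; log2 fold change 1.42, SE 0.11, adjusted p = 5.5e-05). KRT15, a keratin of basal cells, rose by 1.98 (SE 0.24, adjusted p = 4.1e-04), and HKDC1, HMGA2, S100A3, SLC12A8, TNFRSF10D, NT5E and DKK3 rose by 1.39 to 1.72. Of the 10 genes up that the rule took here, 1 is not described. Among genes with a mean of at least 50 and all 6 knockdown libraries on the same side of all 3 controls, the largest falls besides GATA2 and IGF2 were in C19orf21 (-1.57), FAM65A (-1.38, from 2022 ± 89.7 to 784 ± 104), GBP2, SGK223, SEMA6C, PANX2, SLC30A3 and SRM, the spermidine synthase (-1.14, SE 0.20, adjusted p = 0.00308). Outside that filter DUSP2, a phosphatase of ERK, fell by more.

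Of the gene lists, 4 moved up and 2 down in DU145-DR by camera. Of 26 unfolded protein and integrated stress response genes, 11 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.00614). VLDLR rose by 0.93, SEL1L by 0.55 and HSP90B1 by 0.51. Of 12 basal prostate markers, 6 rose and 0 fell, the same adjusted over the list alone (adjusted p = 0.01), among them ITGA6 (0.84) and COL17A1 (1.25). Of 45 mitotic genes, 11 rose and 2 fell (11 and 3 adjusted over the list alone; adjusted p = 0.01), with HMMR at 0.65, BUB3 at 0.52 and BIRC5 at 0.43 while FOXM1 fell. Of 25 drug efflux pumps and tubulins, 9 rose and 1 fell (10 and 4 adjusted over the list alone; adjusted p = 0.0474), including STMN1 (0.71), TUBA1A (0.52) and the efflux pump ABCC2 (1.05). Cholesterol synthesis fell, with 0 of 24 genes up and 3 down (0 and 3 adjusted over the list alone; adjusted p = 0.01): SREBF2, its main transcription factor, by -0.61, DHCR7 by -0.47 and MVK by -0.63. Of 72 cytoplasmic ribosomal protein genes, 0 rose and 4 fell (0 and 2 adjusted over the list alone; adjusted p = 0.00614). None of the 6 calls held with an estimated correlation, where the adjusted p was 0.488 for the stress response, 0.637 for basal markers and cholesterol synthesis and 0.733 for the others. Quantile normalisation ended the calls of mitotic genes and of pumps and tubulins (both at adjusted p = 0.125), and the replicate block ended the latter (0.0509).

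Other lists had members on both sides in DU145-DR without a call for the list. Of 23 TGF-beta and BMP response genes, 2 rose and 6 fell (2 and 9 adjusted over the list alone), with ID1 (-0.88) and ID3 (-0.69) among those that fell. Of 31 hypoxia and glycolysis genes, 7 rose and 2 fell (8 and 2), among them SLC2A3 (1.37), and of 24 Notch and Hedgehog genes 3 rose and 5 fell (3 and 6). Of 28 ERK feedback genes 4 rose and 2 fell (5 and 5), where DUSP2 fell by -2.93 (SE 0.34, adjusted p = 3.3e-04). Of 17 HLA class I and antigen presentation genes 5 rose and 1 fell (5 and 1), and of 25 p53 targets 4 rose and 3 fell (5 and 6). Of 31 mesenchymal genes 5 rose and 2 fell (5 and 2), with ITGB3 at 1.37 and TNC at 1.36. Among NF-kB and inflammatory cytokine genes IL11 (1.04) and IL8 (0.94) rose and CCL20 (-0.70) fell. Of 25 epithelial junction genes 2 rose and 3 fell (2 and 3), of 26 interferon response genes 3 rose and 1 fell (3 and 1), of 25 apoptosis regulators 3 rose and 1 fell (3 and 1), and of 30 nuclear pore genes 4 rose and 2 fell (4 and 2). Of the markers of other cell types, 5 endothelial genes had 2 up and 0 down (ROBO4 at 1.46 and KDR at 1.34; camera adjusted p = 0.316, fry 0.0173), 6 fibroblast genes had 0 up and 1 down (COL1A1 at -0.74; camera adjusted p = 0.343) and 2 blood cell genes had 0 up and 0 down.

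In all, 2231 of 13362 genes passed in DU145-DR (1165 up and 1066 down), and 138 of them changed at least 2-fold. Of the 58 genes with values that were not whole, 34 were among the calls, and without those genes 2175 passed. The replicate block raised the count to 5184 (5149 without the 58 genes), leaving out Control replicate 1 or Control replicate 2 lowered it to 939 or 857, and a fit of all 27 libraries lowered it to 650.

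In 22Rv1-DR, few genes passed once genes with values that were not whole were left out. PREX1, a guanine exchange factor for Rac, had whole values and fell from 4649.8 ± 985 (n = 3) to 1548 ± 186 (n = 6; log2 fold change -1.57, SE 0.16, adjusted p = 0.0115). It was the 1 gene that passed in both settings. With all genes, 55 of 13757 passed (17 up and 38 down), of which 30 were among the 58 genes, and 26 of the 55 changed at least 2-fold. Among calls with whole values, HIST2H2BE (adjusted p = 0.0281), MCFD2 (1.16, adjusted p = 0.0256), ANKRD52 (1.02), HIST1H2AC (1.02), PIK3R3 (0.97), RCAN2 (0.96) and PTPMT1 (1.03) rose. CALD1 (-1.26), SYNPO2 (-1.25) and DUT, an enzyme of nucleotide metabolism (-1.13, adjusted p = 0.0256), fell. Besides IGF2 and GATA2, calls among genes with values that were not whole included TESC (-1.64, 3 of 9), MND1 (-1.41, 3 of 9), SHANK2 (from 239 ± 35.1 to 96.3 ± 12.6, 3 of 9), RPA3 (-1.24, 2 of 9), PBK (-1.13, 2 of 9), CENPF (-1.11, 1 of 9), GPRC5C (1.14, 5 of 9), NRBF2 (1.02, 1 of 9) and PBXIP1 (1.01, 2 of 9). With round offsets removed none of those that could be refitted passed: TESC had -0.97 (adjusted p = 0.2), MND1 -0.59 (0.558), RPA3 -0.35 (0.597) NRBF2 0.87 (0.0932) and CENPF -1.03 (0.127), and SHANK2 changed sign, to 0.29 (0.586). PBK, GPRC5C and PBXIP1 had a value without a single offset and were not refitted.

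Cell cycle lists were lower in 22Rv1-DR. The median log2 fold change was -0.37 over 45 mitotic genes (camera adjusted p = 3.0e-13) and -0.38 over 44 DNA replication genes (adjusted p = 5.3e-07). Of the mitotic genes 5 fell (13 adjusted over the list alone), all 5 among the 58 genes, including NUSAP1, PTTG1, CENPF and CDK1. Without the 58 genes 0 mitotic genes passed over all genes or over the list alone, while camera gave adjusted p = 4.7e-08 with a median of -0.33. Of the replication genes 0 passed by limma in either way. Of 20 replication-dependent histone genes, a list fixed as a sign of RNA selection, 1 rose (4 adjusted over the list alone; median 0.52, adjusted p = 1.5e-05), and the 72 ribosomal protein genes were higher as a list (median 0.11, adjusted p = 0.0322) with 0 members past the threshold. Each of the 4 lists had adjusted p = 0.973 with an estimated correlation, and the ribosomal list had adjusted p = 0.0987 with the replicate block.

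Without the 58 genes the number of calls in 22Rv1-DR went from 55 to 1, and at an unadjusted p under 0.05 there were 1379 genes before their removal. The Benjamini-Hochberg step contributes to that loss: MCFD2 kept its log2 fold change of 1.16 with round offsets removed, while its adjusted p went to 0.0769. The replicate block gave 166 genes (26 without the 58), DESeq2 181, edgeR 57 and a fit of all 27 libraries 224, and leaving out any 1 library other than Control replicate 3 left at most 2.

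In ARCaPM-DR, more genes both passed the threshold and changed at least 2-fold (634) than in DU145-DR (138) or 22Rv1-DR (26). These counts depend on how many genes passed, 2418, 2231 and 55 in these lines, and do not compare the size of change alone. CALCRL, a receptor for calcitonin family peptides, rose from 8.83 ± 1.65 (n = 3) to 229 ± 64.6 (n = 6; log2 fold change 4.52, SE 0.25, adjusted p = 1.1e-05). IFI44L, an interferon-induced gene, rose by 5.17 (SE 0.73), EFHA2 by 4.90, CLIP4 by 3.19 and SPARC, a matrix glycoprotein, by 2.86, followed by HTR2B, TMEM27, LRRN3, LRRTM4 and CCRL1 at 2.64 to 2.78. MTHFD1, a folate enzyme, fell from 3524 ± 219.6 to 811 ± 132 (-2.13, SE 0.12, adjusted p = 1.1e-05), and NCEH1 (-2.19), PAK4 (-2.10), ZNF25, MICALCL, THYN1, CYS1 and the chemokine CCL5 (-2.04) fell by similar amounts. The values of all of these genes were whole in this line.

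Of the lists, 5 moved down and 1 up in ARCaPM-DR. Of 30 hypoxia and glycolysis genes 2 rose and 11 fell (2 and 14 adjusted over the list alone; camera adjusted p = 0.00748), with PDK1 at -1.37 and GPI at -0.70 while the glucose transporter SLC2A3 rose by 2.37. Of 23 NF-kB and inflammatory cytokine genes 1 rose and 5 fell (1 and 10; adjusted p = 0.0124), with NFKBIA at -0.89 and CSF1 at -1.81. Of 32 ERK feedback genes 1 rose and 6 fell (1 and 9; adjusted p = 0.0422), among them FOSL1 (-0.70) and FOSB (-1.18). Of 44 replication genes 0 rose and 6 fell (0 and 2; adjusted p = 0.029), including PCNA (-0.93) and TYMS (-0.64). Of 45 mitotic genes 2 rose and 10 fell (2 and 12; adjusted p = 0.0445), including MAD2L1 (-1.38) and HJURP (-0.64), while BUB3 rose by 0.64. The mitotic call was lost without the 58 genes (adjusted p = 0.0527) and with the block (0.0503). Of 25 replication-dependent histone genes, the list fixed as a sign of RNA selection, 9 rose and 0 fell (9 and 0, camera adjusted p = 3.6e-04), with HIST1H2BK at 1.69. With an estimated correlation the adjusted p was 0.701 for each of these lists except replication (0.756).

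Single members of other lists moved strongly in ARCaPM-DR. Of 26 stress response genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), with the chaperone PDIA4 at 1.40, SEL1L at 1.26 and SLC7A11 at 1.79. HSP90AA1 rose by 1.06 while HSP90AB1 fell by 1.01 and HSPD1 by 1.04, in a list of 16 heat shock genes with 3 up and 4 down (3 and 4). ABCB1, the efflux pump of taxanes, went from 7079 ± 637 to 19597 ± 5356 (1.43, SE 0.20, adjusted p = 0.00119), in a list of 24 pumps and tubulins with 5 up and 2 down (6 and 2). Of 18 insulin-like growth factor genes 3 rose and 3 fell (4 and 5), with IGF1 at 2.55, and of 10 GATA factors and steroid receptor cofactors 2 rose and 2 fell (3 and 2), with the glucocorticoid receptor NR3C1 at 0.93. Of 42 oxidative phosphorylation genes 2 rose and 4 fell (2 and 4), with UQCRC2 at -1.81, and of 10 neuroendocrine markers 2 rose and 1 fell (3 and 1). Of the markers of other cell types, 4 fibroblast genes had 1 up and 1 down, 4 blood cell genes had 0 up and 1 down (CD68, -1.75) and 4 endothelial genes had 1 up and 0 down (EMCN, 1.09), too few for a list test. Mitochondrially encoded transcripts, listed as a sign of RNA quality, had 0 genes in the table.

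In all, 2418 of 13079 genes passed in ARCaPM-DR (1290 up and 1128 down), and 634 of them changed at least 2-fold. Of the 58 genes, 27 were among the calls, and without them 2380 passed. The replicate block gave 5885 (5842 without the 58), and leaving out Control replicate 1, Control replicate 3, shGATA2a replicate 1 or shGATA2b replicate 1 gave 1179, 1351, 1522 or 1588.

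**Figure D3:**
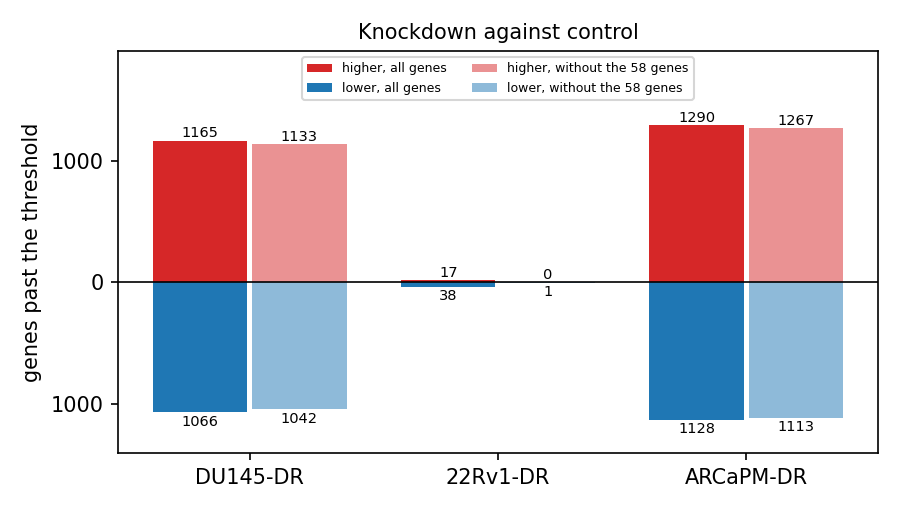
Number of genes past the threshold in knockdown against control, higher (above the line) and lower (below it), in each cell line. Full colours are all genes and pale colours leave out the 58 genes with values that were not whole; the counts in 22Rv1-DR were 17 and 38 with all genes and 0 and 1 without them.

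Both hairpins changed many of the same genes in DU145-DR and ARCaPM-DR. MCFD2, a cargo receptor of the secretory pathway with whole values, rose with shGATA2a and shGATA2b by 1.16 and 1.25 in DU145-DR and by 1.75 and 1.79 in ARCaPM-DR. In DU145-DR, 2146 genes passed with shGATA2a and 777 with shGATA2b, and 707 passed with both in the same direction (408 up and 299 down), where independent lists would give 62.65. In ARCaPM-DR the counts were 1679, 1895 and 1084 (615 up and 469 down; independent lists 121.70), with 5 genes in opposite directions. In 22Rv1-DR limma called 0 genes with shGATA2a (900 at an unadjusted p under 0.05; edgeR 0, DESeq2 97) and 1 with shGATA2b, PREX1 (adjusted p = 0.0399; edgeR 1, DESeq2 91), so 0 were shared (edgeR 0, DESeq2 76). Without the 58 genes 2097, 730 and 666 genes passed with shGATA2a, shGATA2b and both in DU145-DR and 1640, 1856 and 1050 in ARCaPM-DR. Simulated unchanged hairpins against the same controls shared 0 genes. The simulation drew genes and libraries independently, without the structure by replicate number. Splits of the real libraries, other than the real grouping, shared at most 2 genes in DU145-DR, 28 in 22Rv1-DR and 888 in ARCaPM-DR. The simulated values can thus understate what unchanged groups share. The covariance of the fold changes was 0.1054, 0.0985 and 0.2585 in DU145-DR, 22Rv1-DR and ARCaPM-DR against 0.0186, 0.0385 and 0.0378 in the simulation, and the correlation across genes, which are not independent replicates, was 0.84, 0.90 and 0.81 against 0.50. The 3 controls could not be split, so part of the excess may come from sharing them. With the replicate block 2875, 61 and 3580 genes were shared in the 3 lines (5089, 83 and 5223 with shGATA2a, 3515, 66 and 5278 with shGATA2b). In DU145-DR, shGATA2a alone called 1034, 948, 1054 or 1317 genes without Control replicate 1, Control replicate 2, shGATA2a replicate 1 or shGATA2a replicate 2. There shGATA2b alone called 120, 146, 511, 195 or 341 without Control replicate 1, Control replicate 2, shGATA2a replicate 2, shGATA2b replicate 1 or shGATA2b replicate 3. In ARCaPM-DR, shGATA2a called 773, 948, 654 or 2997 without Control replicate 1, Control replicate 3, shGATA2a replicate 1 or shGATA2a replicate 2, and shGATA2b 1034, 1111, 880 or 1079 without Control replicate 1, Control replicate 3, shGATA2b replicate 1 or shGATA2b replicate 3. A fit of all 27 libraries called 532, 118 and 112 genes with shGATA2a, shGATA2b and both in DU145-DR and 112, 82 and 72 in 22Rv1-DR. In DU145-DR the shared count was 117 without Control replicate 1, 139 without Control replicate 2, 183 without shGATA2b replicate 1, 305 without shGATA2b replicate 3 and 459 without shGATA2a replicate 2. In ARCaPM-DR it was 529 without Control replicate 1, 626 without Control replicate 3, 502 without shGATA2a replicate 1, 1637 without shGATA2a replicate 2 and 610 without shGATA2b replicate 1.

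Between the hairpins, ARCaPM-DR showed differences in single genes. HMOX1, a heme-degrading stress enzyme, was higher with shGATA2b than with shGATA2a by 2.85 (adjusted p = 0.00231), as were NOG (1.87) and PLOD3 (1.84), while GZMB (-2.61), SERPINA6 (-2.53) and STT3B (-1.89, adjusted p = 0.00228) were lower. In all, 105 genes passed there (27 up and 78 down, 1 of them among the 58), 1629 with the replicate block, 388 with DESeq2 and 252 in a fit of all 27 libraries. Leaving out replicates 1, 2 or 3 of shGATA2a gave 10, 281 or 35, of shGATA2b 14, 29 or 33, and Control replicates 1 or 3 gave 52 or 64. In DU145-DR limma called 0 genes (787 at an unadjusted p under 0.05; edgeR 0, DESeq2 12, replicate block 290), and in 22Rv1-DR 0 (13 at an unadjusted p under 0.05; edgeR 0, DESeq2 0, replicate block 0).

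Across the lines, MCFD2 rose and GATA2 fell in each. The average knockdown effect was 1.38 for MCFD2 (SE 0.07, adjusted p = 3.3e-12) and -2.04 for GATA2 (SE 0.12, adjusted p = 1.9e-11), and PTPMT1, a mitochondrial phosphatase, rose by 1.31 (SE 0.10). VAMP7 (average 1.34) and CALU (1.28) rose and PAK4 (-1.29) and IGF2 (-2.54) fell in each line. Of the 27 IGF2 values 23 were not whole. The values of VAMP7, CALU and PAK4 were whole in ARCaPM-DR, while in DU145-DR 2, 0 and 2 of 9 and in 22Rv1-DR 1, 1 and 3 of 9 were not. GATA2 had 5 and 7 of 9 there. With round offsets removed VAMP7 (0.82, adjusted p = 0.0885) and CALU (0.84, adjusted p = 0.0871) did not pass in 22Rv1-DR. In all, 14 genes were called in the same direction in each of the 3 lines (9 up and 5 down, where independent lists would give 0.13 and 0.23), and 12 of them were among the 58 genes. The other 2 were MCFD2 and PTPMT1. Without the 58 genes limma left 0 such genes, as MCFD2 and PTPMT1 did not pass in 22Rv1-DR, and the replicate block gave 6: DUT, PDK4, PIK3R3, RPIA, SLC43A2 and UROS, of which PDK4, RPIA, SLC43A2 and UROS lie outside the rule and were named after their values were seen. With all genes edgeR gave 14, DESeq2 40 and the block 57, and leaving out any 1 library of 22Rv1-DR other than Control replicate 3 left 0 or 1.

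DU145-DR and ARCaPM-DR shared 466 calls in the same direction (294 up and 172 down; independent lists 103.65 and 90.62) and 110 in opposite directions (independent lists 193.86). With the block these counts were 1866 and 635, and without the 58 genes 433 and 107. The correlation of fold changes across genes was 0.29 for this pair, 0.44 for 22Rv1-DR and ARCaPM-DR and 0.18 for DU145-DR and 22Rv1-DR. On average over the lines 2809 of 15295 genes passed (1385 up and 1424 down), 2754 without the 58 genes and 5535 with the block. Of the averaged lists, 2 moved down and 1 up. The mitotic list, 1 of the 2, was called up in DU145-DR and down in the other lines. Its average thus covers opposite directions. Of 44 replication genes 0 rose and 10 fell (0 and 12 adjusted over the list alone; camera adjusted p = 3.1e-04), of 45 mitotic genes 2 rose and 15 fell (2 and 16; adjusted p = 8.8e-04, but 0.0603 without the 58 genes), and of 25 replication-dependent histone genes 9 rose and 0 fell (9 and 0; adjusted p = 3.8e-04). The histone list was fixed as a sign of RNA selection, since transcripts of such genes mostly lack a poly(A) tail. Whether this holds for the members that rose was not tested, so their rise does not show a difference in RNA selection. With an estimated correlation each had adjusted p = 0.758.

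The size of the knockdown effect differed between lines for 1071 genes (1030 without the 58 genes, 4003 with the block). ITPRIPL2 rose by 0.28 in DU145-DR and fell by 1.76 in ARCaPM-DR, with -0.55 in 22Rv1-DR (adjusted p for the difference 3.3e-07). TOMM22, a subunit of the mitochondrial import pore, had 0.25, -0.83 and -1.76 in DU145-DR, 22Rv1-DR and ARCaPM-DR (6.6e-07), and NCEH1, a cholesteryl ester hydrolase, had 0.48, -0.77 and -2.19 (1.2e-06). UQCRC2, a subunit of respiratory complex III, had 0.02, -0.43 and -1.81 (1.2e-06), and PTPN14, a tyrosine phosphatase, had 0.62, 0.45 and 2.17 (1.5e-06). All values of these 5 genes were whole. In pairs, 1090 genes differed between ARCaPM-DR and DU145-DR (3138 with the block), 519 between ARCaPM-DR and 22Rv1-DR (2280) and 166 between 22Rv1-DR and DU145-DR (1571). Leaving out the 58 genes, with no block, gave 1076, 488 and 140. The joint fit kept genes at 10 or more in any 3 of the 27 libraries. A gene near 0 in a line could thus enter this test and the average with no effect there. KLK3, at 0 in DU145-DR and ARCaPM-DR controls, had 0.00, -1.37 and 0.00 in DU145-DR, 22Rv1-DR and ARCaPM-DR (adjusted p for the difference 0.0175). The number of such genes was not counted.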

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

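Tests of the origin of the values that were not whole, of the spread and depth in 22Rv1-DR, and all settings that left out or altered those genes and the splits within replicate numbers were chosen after the result was seen, and the other tests were planned.

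The knockdown effect differed between the cell lines for 1071 genes by a test of the difference itself. The genes with the smallest p were ITPRIPL2 (adjusted p = 3.3e-07), TOMM22 (6.6e-07), NCEH1 (1.2e-06), UQCRC2 (1.2e-06) and PTPN14 (1.5e-06). ITPRIPL2 and NCEH1 rose in DU145-DR and fell in ARCaPM-DR, and the cause of the differences was not tested. Of 100 splits of the libraries within lines, 2 gave as many genes, the real one included, with 1819 in the highest other. A split with more genes than the real one points to a structure of the samples. Of 100 splits that exchange libraries only within a replicate number, 1 gave as many, the real one (highest other 839). Either kind of split removes the knockdown effect as well as its difference between lines. Neither share can therefore exclude chance for the difference between lines.

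The values that were not whole reads, 199 in 58 genes, were the first pattern weighed. Counting reads in parts between similar genes would leave a gene's values not whole in most libraries, but the median gene had them in 11.1% of libraries, and rounding is argued against by 99.945% of the 359711 values at least as large being whole. Removing a multiple of 100 made 137 of the values whole (highest comparison base 31), and a multiple of 10 up to 500 made 164 whole (highest comparison base 59), which is consistent with round numbers added to or subtracted from scaled counts, though only 155 values had a single offset, 35 had none and 9 had several. With the offsets removed, 0 of 16 calls among genes with every offset found were left in 22Rv1-DR (4 of 16 at the largest unadjusted p called before). The median absolute log2 fold change there was 0.96 before and 0.55 after. Of 25 calls outside the 58 genes 1 was left by adjusted p, while 25 of 25 were left at that largest unadjusted p. The loss of calls outside the 58 genes is thus one of multiple testing. In DU145-DR 13 of 14 were left, against the result written in advance, while the median absolute change went from 0.92 to 0.66. Every call among genes with every offset found had a smaller absolute fold change after removal, and SHANK2 changed sign. In these calls the offsets found in controls were above 0 for genes that fell and below 0 for genes that rose. In 22Rv1-DR 16 of the 37 genes with every offset found were calls on the deposited values. Picking calls favours offsets that widen a change there. In DU145-DR 14 of 14 such genes were calls, so picking calls left out none. The choice of calls thus does not account for the direction of the offsets in DU145-DR. The set of genes in this refit was redefined per line after a first result. How and at what step such numbers entered, and whether the 20 genes without an offset for each value share that origin, stays open, no biological explanation was tested, and permuting the labels cannot detect altered values.

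The few calls in 22Rv1-DR were the second pattern. Control replicate 3 stood apart from the other controls (chi-square per degree of freedom 112 and 108, against 24.7 between those). Without it and the 58 genes 5 genes passed, in a fit with a group of 2 controls. Leaving out a control of DU145-DR or ARCaPM-DR still left at least 857 and 1179 genes with all genes kept. This argues against Control replicate 3 as the sole cause, while a part in the spread stays open. Low depth is argued against by a median of 13.02 M reads, above that of ARCaPM-DR. A wide spread between libraries stays open: the simulation, run without the replicate block, recovered 79.10% of 2-fold changes, more than in ARCaPM-DR, but 10.45% of 1.5-fold changes. With the replicate block 166 genes passed, or 26 without the 58 genes, against 5149 in DU145-DR without them. Removing the spread between replicate numbers thus left few calls in 22Rv1-DR. A weaker response of this line is untested.

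The 105 genes that differed between the hairpins in ARCaPM-DR were the third pattern. Without the shallow library shGATA2a replicate 3, 35 genes passed. Leaving out shGATA2a replicate 1 or shGATA2b replicate 1, 2 or 3 gave 10, 14, 29 or 33, while shGATA2a replicate 2 gave 281. The drop is not particular to the shallow library, and its part stays open. GATA2 was lower with shGATA2b by a log2 fold change of -0.75 (SE 0.25, adjusted p = 0.257), which neither excludes an unequal loss of GATA2 nor shows that it accounts for the other genes. Off-target effects of a hairpin were not tested.

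The counts of splits in this paragraph include the real grouping. For knockdown against control, all 84 splits of the 9 libraries of a line were counted. In DU145-DR 1 gave as many genes, the real one (2231 genes, highest other 462). In ARCaPM-DR 1 did as well, the real one (2418, highest other 1156). Both shares argue against chance if libraries can be exchanged freely, which is not assured, since the replicate numbers pair the samples. In 22Rv1-DR 2 of 84 gave as many genes, the real one and another (55 genes, highest other 960). That other split set the 3 libraries numbered 3 against the rest, which points to a structure by replicate number, and the blocked count was 166. Of the 55 calls in the real grouping of 22Rv1-DR, 30 were among the 58 genes, and without those genes 1 gene passed. The splits counted the 58 genes as well, so no conclusion about chance is drawn from that share in 22Rv1-DR. Among the 27 splits that take 1 library of each number as control, the highest other counts were 462, 0 and 658 in DU145-DR, 22Rv1-DR and ARCaPM-DR. For genes called with both hairpins, 1 of 100 splits gave as many in DU145-DR (707, highest other 2) and in ARCaPM-DR (1084, highest other 888). Both shares argue against chance under the same limit on free exchange. In 22Rv1-DR the real count was 0, so 100 of 100 splits reached it by construction (highest other 28) and the test says nothing there. For the average effect 1 of 100 splits gave as many (2809, highest other 1498). For genes called in all 3 lines 1 of 100 did (14, highest other 0), but 12 of the 14 were among the 58 genes. Without those genes the real count was 0, so no conclusion is drawn from that share. Of 100 splits within replicate numbers, with the exchange of both hairpins counted as the real one, 1 gave as many for both hairpins in DU145-DR (highest other 0) and ARCaPM-DR (highest other 757), for all 3 lines (highest other 0) and for the average effect (highest other 170). These shares say nothing about the 58 genes, nor about the count over all 3 lines that rests on them. Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. The real and highest other counts were 2146 and 0, 0 and 0 and 1679 and 0 for shGATA2a in DU145-DR, 22Rv1-DR and ARCaPM-DR, 777 and 0, 1 and 0 and 1895 and 0 for shGATA2b, and 0 and 0, 0 and 0 and 105 and 0 between the hairpins.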

How the results depend on the processing

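Leaving out the 58 genes, removing offsets, edgeR and DESeq2 were chosen after the data were seen, and the other settings were planned. Of 12 planned and 5 added settings, the fold threshold, camera, fry and both settings without the 58 genes scored no named genes. Under the others, named genes besides GATA2 gave 5273 values with the call, or the lack of one, kept. A change of sign between values that did not pass counts among these. Another 799 values kept direction but no longer passed, 24 newly passed and 1 reversed, SHANK2 in 22Rv1-DR (0.29 with round offsets removed). Quantile and median of ratios scaling kept the direction of every called list and moved the median of all genes by 0.02 at most. The quantile setting newly called ribosomal proteins in ARCaPM-DR (adjusted p = 0.00346) and hypoxia on average (0.0374). The block newly called hypoxia on average (0.0113) and, beyond the list calls it ended, changed no other list.

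A fold threshold of at least 2 in addition, fewer genes by construction, gave 138 for knockdown in DU145-DR, 204 for shGATA2a in DU145-DR, 74 for shGATA2b in DU145-DR, 60 for both hairpins in DU145-DR, 26 for knockdown in 22Rv1-DR and 634 for knockdown in ARCaPM-DR. It also gave 591 for shGATA2a in ARCaPM-DR, 670 for shGATA2b in ARCaPM-DR, 47 for the hairpin difference in ARCaPM-DR, 368 for both hairpins in ARCaPM-DR, 83 for average effect and 605 for difference between lines. It also gave 3 for called in all 3 lines. Camera with an estimated correlation gave 0 for lists in DU145-DR, 0 for lists in 22Rv1-DR, 0 for lists in ARCaPM-DR and 0 for lists on average. Fry gave 0 for lists in 22Rv1-DR and 1 for lists on average. A fit of all 27 libraries gave 650 for knockdown in DU145-DR, 532 for shGATA2a in DU145-DR, 118 for shGATA2b in DU145-DR, 112 for both hairpins in DU145-DR, 224 for knockdown in 22Rv1-DR and 112 for shGATA2a in 22Rv1-DR. It also gave 82 for shGATA2b in 22Rv1-DR, 72 for both hairpins in 22Rv1-DR, 252 for the hairpin difference in ARCaPM-DR, 3 for lists in ARCaPM-DR and 39 for called in all 3 lines. Quantile normalisation gave 1 for shGATA2a in 22Rv1-DR and 1 for both hairpins in 22Rv1-DR. Median of ratios scaling gave 1 for shGATA2a in 22Rv1-DR and 1 for both hairpins in 22Rv1-DR. The replicate block, in a design whose numbers pair the samples, gave 5184 for knockdown in DU145-DR, 5089 for shGATA2a in DU145-DR, 3515 for shGATA2b in DU145-DR, 290 for the hairpin difference in DU145-DR, 2875 for both hairpins in DU145-DR and 166 for knockdown in 22Rv1-DR. It also gave 83 for shGATA2a in 22Rv1-DR, 66 for shGATA2b in 22Rv1-DR, 61 for both hairpins in 22Rv1-DR, 5885 for knockdown in ARCaPM-DR, 5223 for shGATA2a in ARCaPM-DR and 5278 for shGATA2b in ARCaPM-DR. It also gave 1629 for the hairpin difference in ARCaPM-DR, 3580 for both hairpins in ARCaPM-DR, 5535 for average effect, 4003 for difference between lines and 57 for called in all 3 lines. Without a trend the counts were 333 for shGATA2b in DU145-DR, 312 for both hairpins in DU145-DR, 3 for knockdown in 22Rv1-DR, 0 for shGATA2b in 22Rv1-DR, -1.71 for GATA2 in 22Rv1-DR (adjusted p = 0.0571) and 56 for the hairpin difference in ARCaPM-DR. It also gave 0 for called in all 3 lines. Without the 58 genes the counts were 1 for knockdown in 22Rv1-DR and 0 for called in all 3 lines. Without the 58 genes and with the replicate block they were 5149 for knockdown in DU145-DR, 5049 for shGATA2a in DU145-DR, 3477 for shGATA2b in DU145-DR, 292 for the hairpin difference in DU145-DR, 2840 for both hairpins in DU145-DR and 26 for knockdown in 22Rv1-DR. It also gave 7 for shGATA2a in 22Rv1-DR, 6 for shGATA2b in 22Rv1-DR, 5 for both hairpins in 22Rv1-DR, 5842 for knockdown in ARCaPM-DR, 5179 for shGATA2a in ARCaPM-DR and 5236 for shGATA2b in ARCaPM-DR. It also gave 1608 for the hairpin difference in ARCaPM-DR, 3546 for both hairpins in ARCaPM-DR, 6 for called in all 3 lines, 5471 for average effect and 3949 for difference between lines. With round offsets removed they were 1 for knockdown in 22Rv1-DR and 0 for called in all 3 lines. DESeq2 on the recovered reads gave 1353 for shGATA2b in DU145-DR, 12 for the hairpin difference in DU145-DR, 1148 for both hairpins in DU145-DR, 181 for knockdown in 22Rv1-DR, 97 for shGATA2a in 22Rv1-DR and 91 for shGATA2b in 22Rv1-DR. It also gave 76 for both hairpins in 22Rv1-DR, 388 for the hairpin difference in ARCaPM-DR, 40 for called in all 3 lines and 1819 for difference between lines. The cause was not tested.

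Leaving out 1 library at a time, with a group of 2 assumed to vary like the others, gave these ranges. Average effect ran from 2160 to 3496. Both hairpins in 22Rv1-DR stayed at 0. Both hairpins in ARCaPM-DR ran from 502 to 1637, leaving 1.5 times without Control 1 (529), shGATA2a 1 (502), shGATA2b 1 (610), shGATA2a 2 (1637), Control 3 (626). Both hairpins in DU145-DR ran from 117 to 1013, leaving 1.5 times without Control 1 (117), shGATA2b 1 (183), Control 2 (139), shGATA2a 2 (459), shGATA2b 3 (305). GATA2 in 22Rv1-DR ran from -1.85 to -1.57, with adjusted p from 0.063 to 0.11 and no call without Control 1 (-1.73), shGATA2a 1 (-1.68), shGATA2b 1 (-1.58), Control 2 (-1.57), shGATA2a 2 (-1.80), shGATA2a 3 (-1.63), shGATA2b 3 (-1.69). GATA2 in ARCaPM-DR ran from -2.68 to -2.48. GATA2 in DU145-DR ran from -1.98 to -1.76. Called in all 3 lines ran from 0 to 15, leaving 1.5 times without Control 1 (0), shGATA2a 1 (0), shGATA2b 1 (1), Control 2 (0), shGATA2a 2 (0), shGATA2b 2 (1), shGATA2a 3 (0), shGATA2b 3 (0). Knockdown in 22Rv1-DR ran from 0 to 37, leaving 1.5 times without Control 1 (0), shGATA2a 1 (0), shGATA2b 1 (2), Control 2 (1), shGATA2a 2 (2), shGATA2b 2 (2), shGATA2a 3 (1), shGATA2b 3 (1). Knockdown in ARCaPM-DR ran from 1179 to 3545, leaving 1.5 times without Control 1 (1179), shGATA2a 1 (1522), shGATA2b 1 (1588), Control 3 (1351). Knockdown in DU145-DR ran from 857 to 2440, leaving 1.5 times without Control 1 (939), Control 2 (857). Difference between lines ran from 721 to 1509. ShGATA2a in 22Rv1-DR ran from 0 to 1, leaving 1.5 times without shGATA2b 1 (1). ShGATA2a in ARCaPM-DR ran from 654 to 2997, leaving 1.5 times without Control 1 (773), shGATA2a 1 (654), shGATA2a 2 (2997), Control 3 (948). ShGATA2a in DU145-DR ran from 948 to 2432, leaving 1.5 times without Control 1 (1034), shGATA2a 1 (1054), Control 2 (948), shGATA2a 2 (1317). ShGATA2b in 22Rv1-DR ran from 0 to 1, leaving 1.5 times without Control 1 (0), shGATA2a 1 (0), shGATA2b 1 (0), Control 2 (0), shGATA2a 2 (0), shGATA2b 2 (0), shGATA2a 3 (0), shGATA2b 3 (0). ShGATA2b in ARCaPM-DR ran from 880 to 2598, leaving 1.5 times without Control 1 (1034), shGATA2b 1 (880), Control 3 (1111), shGATA2b 3 (1079). ShGATA2b in DU145-DR ran from 120 to 1151, leaving 1.5 times without Control 1 (120), shGATA2b 1 (195), Control 2 (146), shGATA2a 2 (511), shGATA2b 3 (341). The hairpin difference in 22Rv1-DR stayed at 0. The hairpin difference in ARCaPM-DR ran from 10 to 281, leaving 1.5 times without Control 1 (52), shGATA2a 1 (10), shGATA2b 1 (14), shGATA2a 2 (281), shGATA2b 2 (29), Control 3 (64), shGATA2a 3 (35), shGATA2b 3 (33). The hairpin difference in DU145-DR ran from 0 to 7, leaving 1.5 times without shGATA2b 3 (7). The cause was not tested beyond the smaller number of libraries.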

Other observations

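The tests in this part were planned, except those on genes with values that were not whole.

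In ARCaPM-DR, TGFBR2, a TGF-beta receptor, rose by 1.54 (SE 0.17, adjusted p = 3.5e-04) while TGFBR1, its partner, fell by 1.67 (SE 0.19, adjusted p = 3.5e-04), in a list of 24 TGF-beta and BMP response genes with 1 up and 3 down (1 and 3 adjusted over the list alone). Of 17 antigen presentation genes 1 rose and 3 fell (1 and 4), with ERAP1 at 1.07 and HLA-E at -1.09. Of 28 epithelial junction genes 5 rose and 3 fell (5 and 4), with CLDN1 at 1.91, TJP1 at 0.54 and OCLN at -0.74. Of 28 mesenchymal and matrix genes 5 rose and 2 fell (6 and 2), with POSTN at 2.29 and COL3A1 at 2.01. Of the 4 fibroblast markers tested COL3A1 was the 1 that rose and COL6A3 (-0.86) the 1 that fell. Interferon genes had 7 up and 2 down of 36 (8 and 2), with IFI6 at 1.34 and SAMD9 at 1.68.

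ITGB3, an integrin subunit, rose by 1.37 in DU145-DR (adjusted p = 5.5e-05) and fell by 1.31 in ARCaPM-DR (adjusted p = 0.00567), and DUSP4, a phosphatase of ERK, rose by 0.59 in DU145-DR and fell by 1.57 in ARCaPM-DR. ABCB1 stood at 70231 ± 10967 (SD, n = 3) in DU145-DR controls, at 14486 ± 1918 in 22Rv1-DR and at 7079 ± 637 in ARCaPM-DR. Its knockdown effect was 0.01, 0.06 and 1.43 in these lines, and the test of the difference between lines gave adjusted p = 6.0e-04. Markers of other cell types had low medians in controls, with values of 0.743, 3.24 and 0.719 for fibroblast, 0.217, 2.09 and 0 for blood cell and 1.01, 1.05 and 1.60 for endothelial genes in DU145-DR, 22Rv1-DR and ARCaPM-DR. Single members stood far above them: 6, 5 and 4 of 15 fibroblast markers were at 10 or more, among them COL6A3 at 31324 ± 2936 and COL3A1 at 2198 ± 1027 in ARCaPM-DR controls.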
